A study of Mus musculus with 6 samples.

How the data were processed

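Mouse embryonic stem (ES) cells, stably transduced with lentivirus for wild-type KBP or for the mutant KBP(KK/RR), were profiled by RNA sequencing in 6 libraries, 3 per group. Per the labels' protocols, total RNA was depleted of ribosomal RNA with RiboZero and made into libraries with ScriptSeq v2. Per the submitters' processing notes, the tools were bcl2fastq, TopHat, HTSeq and DESeq2 (no versions given) and the builds mm10 and GRCm38. The annotation used for counting, the strand setting and any filter are not given in the sources used here. The deposited tables hold raw read counts per gene symbol, as whole numbers, and a normalized signal in which, by its values, the authors divided each count by 1 factor per library. With the factor removed, 100% of the values above 0 in that signal table came out as whole reads within a tolerance of 0.01, and 0 of these reads differed from the raw counts.

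The raw counts were tested as deposited. Library totals ran from 24131743 to 32160411 counts, which limits low-count genes most. Of 23420 gene symbols, 4360 had no count in any library, and 14340 passed edgeR's filterByExpr. Symbols were matched to RefSeq on GRCm38.p6: 21571 by symbol, 1663 by an older synonym, 27 symbols stood as calendar dates and 159 had no match. Transcript length and GC content came from the longest GENCODE M21 transcript per gene, with a value for 23042 symbols. Mitochondrially encoded genes were not analysed here, so the list of their proteins was not tested.

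Groups were compared with edgeR 4.0.16 under R 4.3.3 (TMM factors, quasi-likelihood fit with robust dispersions, glmQLFTest, group as the model's term), and Benjamini-Hochberg adjusted p-values under 0.05 were called. Log2 fold changes are KBP(KK/RR) minus wild-type KBP, and the standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled totals and are given as mean ± SD over 3 libraries. Of 33 gene lists fixed before the data were examined, the 32 with at least 5 tested members were tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. With a preset correlation camera takes its degrees of freedom from the number of genes, and with an estimated one from the 6 libraries. P-values of these settings therefore differ in more than the correlation. For each list the calls over all genes tested and those adjusted over the list alone are given. The libraries' composition was compared with exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Chromosomes were compared by the median log2 fold change of genes with a mean log2 CPM of at least 1, against 10000 random gene sets of the same size.

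The genes named were chosen by a rule written before the data were examined: the KBP gene; the 10 largest increases and 10 largest decreases among called genes whose groups do not overlap, with a mean log2 CPM of at least 2 and a symbol that is not a clone, pseudogene or structural RNA name; up to 3 members per list with the smallest p, and for pluripotency, KBP partner and mitochondrial lists up to 3 with the highest CPM; and Pou5f1, Nanog and Sox2. Other genes are said to be chosen after their values were seen. A few genes that the rule names are not reported here, and all tests and counts include them.

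The procedure was tested on simulated counts for the same comparison, over 14340 genes with 200 changed. The test found 49.3% of genes changed 1.2-fold, 83.6% of those changed 1.5-fold and 90.9% of those changed 2-fold. It called 18 unchanged genes in that simulation, and 4 genes when nothing was changed. Those 18 were a larger share of the simulated calls than the adjusted p threshold aims to allow. The calls in the measured libraries may likewise hold more false ones than that threshold aims for. A simulated trend on transcript length gave 334 calls, and 0 once a smooth trend on length and GC content was removed. That trend followed the same length measure that the correction fits, so its removal does not show that a bias of another form would be removed. The correction would equally remove a true difference between the groups that followed length.

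Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, limma on log2 of the authors' normalized signal plus 1, other scalings, other filters on low counts, structural RNAs left out, a test against a fold of 1.5, adjusted p thresholds of 0.01 and 0.1, an estimated correlation in camera, and each library left out in turn. Removing a trend on length and GC content per library (splines with 5 degrees of freedom, through offsets), for genes, lists and chromosomes, and the test on the recovered reads, were chosen after seeing the data. The replicate libraries of each group differed by more than counting noise, with a chi-square per degree of freedom of 2.69 to 7.19, so none was treated as a duplicate. The labels do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical.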

Results

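Transcript levels were measured in mouse ES cells kept in self-renewing conditions after stable transduction with wild-type KBP (replicates 1, 2 and 3) or with KBP(KK/RR) (replicates 4, 5 and 6), a mutant that the labels call stable. KBP is the Kif1-binding protein, which binds kinesin motors. The comparison asks how transcript levels differ between cells given the mutant and cells given the wild-type protein, since cells without either virus were not part of the design. Total counts were 26059701, 32160411 and 24131743 in the wild-type KBP libraries and 29863560, 24300832 and 29746764 in the KBP(KK/RR) libraries. In a principal component analysis of log2 CPM, component 1 held 31.1% of the variance and separated the groups, and component 2 held 20.8% and set wild-type KBP replicate 3 apart.

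The KBP gene itself (2510003E04Rik in the files, now Kifbp; chromosome 10, 62558470 to 62579066 on GRCm38) rose from 48.3 ± 1.30 CPM in wild-type KBP cells to 56.6 ± 2.88 CPM in KBP(KK/RR) cells. Its log2 fold change was 0.23 (SE 0.05, edgeR adjusted p = 0.0133). Of the 17 tested members of the list of KBP and its partners, 3 rose and 0 fell, and the same numbers held adjusted over the list alone. The other risers were Skp1a, a core subunit of SCF ubiquitin ligases (280 ± 13.0 against 326 ± 12.6 CPM, log2 fold change 0.22, SE 0.04), and Fbxo15, an F-box protein expressed in ES cells (107 ± 1.40 against 119 ± 0.596 CPM, log2 fold change 0.15, SE 0.04). The ligase scaffold Cul1 had a log2 fold change of 0.06 and Stmn2 of 0.02, neither past the threshold (edgeR adjusted p 0.442 and 0.837). The list as a whole was not called (camera adjusted p = 0.276). The count of the KBP gene holds transcripts of the endogenous gene and any that map from the vector, which the table does not separate. Its call was lost without wild-type KBP replicate 2 (adjusted p = 0.0908) or KBP(KK/RR) replicate 5 (0.0735). The Skp1a call was lost without KBP(KK/RR) replicate 6 (0.0608). The Fbxo15 call was lost without wild-type KBP replicate 1 (0.0718), 2 (0.165) or 3 (0.101), KBP(KK/RR) replicate 5 (0.0862) or 6 (0.141), or with a trend on length and GC content removed (0.0627).

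Across the transcriptome, 448 of 14340 tested genes changed, 151 of them higher and 297 lower in KBP(KK/RR) cells, and most changes were small. The median fold change was 1.22 among the higher genes and 0.843 among the lower ones, and 45 genes changed at least 1.5-fold, 30 up and 15 down. Over all called genes the log2 fold change ran from -5.39 to 1.61. The largest increases by the naming rule were Arl14epl (chromosome 18, 46921812 to 46934222; 4.31 ± 0.233 against 6.996 ± 0.243 CPM, log2 fold change 0.69, SE 0.10), the X-linked homeobox gene Rhox5 (log2 fold change 0.66) and Plac8 (0.64). They were followed by the heparan sulfate 6-O-sulfotransferase Hs6st2 (0.61), Pnma5 (0.60), the T-box gene Tbx4 (0.52), Chst15 (0.49), T (0.49) and Sdk2 (0.48). Klhl13 (chromosome X, 23219271 to 23365161) rose from 47.0 ± 1.65 to 65.6 ± 1.04 CPM, a log2 fold change of 0.48 (SE 0.05). The largest decreases by the same rule, with its bound on mean log2 CPM, were the homeobox gene Nkx6-3 (chromosome 8, 23153271 to 23158948, 6.82 ± 0.649 against 4.24 ± 0.582 CPM, log2 fold change -0.70, SE 0.12), Pgpep1l (-0.55) and Cabp1 (-0.53). They were followed by Ms4a6c (-0.51), the postsynaptic scaffold gene Shank1 (-0.49), the cadherin gene Celsr3 (-0.49), Esam (-0.48), the POU-domain gene Pou4f2 (-0.48) and the synaptic vesicle priming gene Unc13a (-0.47). The cytolinker gene Plec (chromosome 15, 76170974 to 76231378) fell from 176 ± 10.8 to 128 ± 8.18 CPM, a log2 fold change of -0.46 (SE 0.05). The edgeR adjusted p was 6.95e-06 for Klhl13, 4.98e-05 for Plec, 1.80e-04 for Pou4f2 and 4.27e-04 for Arl14epl.

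Of the 448 calls, 445 had groups that did not overlap, as did 22.4% of all tested genes, where chance gives 10%. An unadjusted p under 0.05 was reached by 2667 genes, against 717 by chance, and DESeq2 called 307. Of the 20 genes above, 16 had no DESeq2 adjusted p, left out by its filter on mean counts, and the other 4 (Klhl13, Celsr3, Pou4f2 and Plec) were called. In the test against a fold of 1.5, 1 gene passed, Pglyrp3, named here after its values were seen. It had 56 counts over the wild-type KBP libraries and 1 over the KBP(KK/RR) libraries (ratio 0.0175, 95% exact binomial interval 4.35e-04 to 0.101, counting error only; edgeR glmTreat adjusted p = 0.00193). The number of changed genes was 174 without wild-type KBP replicate 2 and 277 without wild-type KBP replicate 3. It was 767 without KBP(KK/RR) replicate 4, 281 without replicate 5 and 122 without replicate 6. Without wild-type KBP replicate 1 there were 98 higher genes. With upper-quartile scaling the calls split into 235 higher and 205 lower.

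Among the 20 genes, edgeR calls were lost without KBP(KK/RR) replicate 6 for Hs6st2 (adjusted p = 0.0562), Pnma5 (0.0649), Chst15 (0.0797), T (0.121), Sdk2 (0.0649), Shank1 (0.131) and Esam (0.0888). Without KBP(KK/RR) replicate 5 those of Sdk2 (0.0622), Ms4a6c (0.0558) and Celsr3 (0.0890) were lost, and without KBP(KK/RR) replicate 4 that of Tbx4 (0.0654). Without wild-type KBP replicate 1 those of Tbx4 (0.0645) and Sdk2 (0.104) were lost. Without wild-type KBP replicate 2 those of Hs6st2 (0.0542), Tbx4 (0.0658), Chst15 (0.0503) and Shank1 (0.117) were lost, and without replicate 3 those of T (0.0719) and Celsr3 (0.148). Shank1 and Unc13a lost their calls with a trend on length and GC content removed (adjusted p 0.180 and 0.0877).

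**Figure D1:**
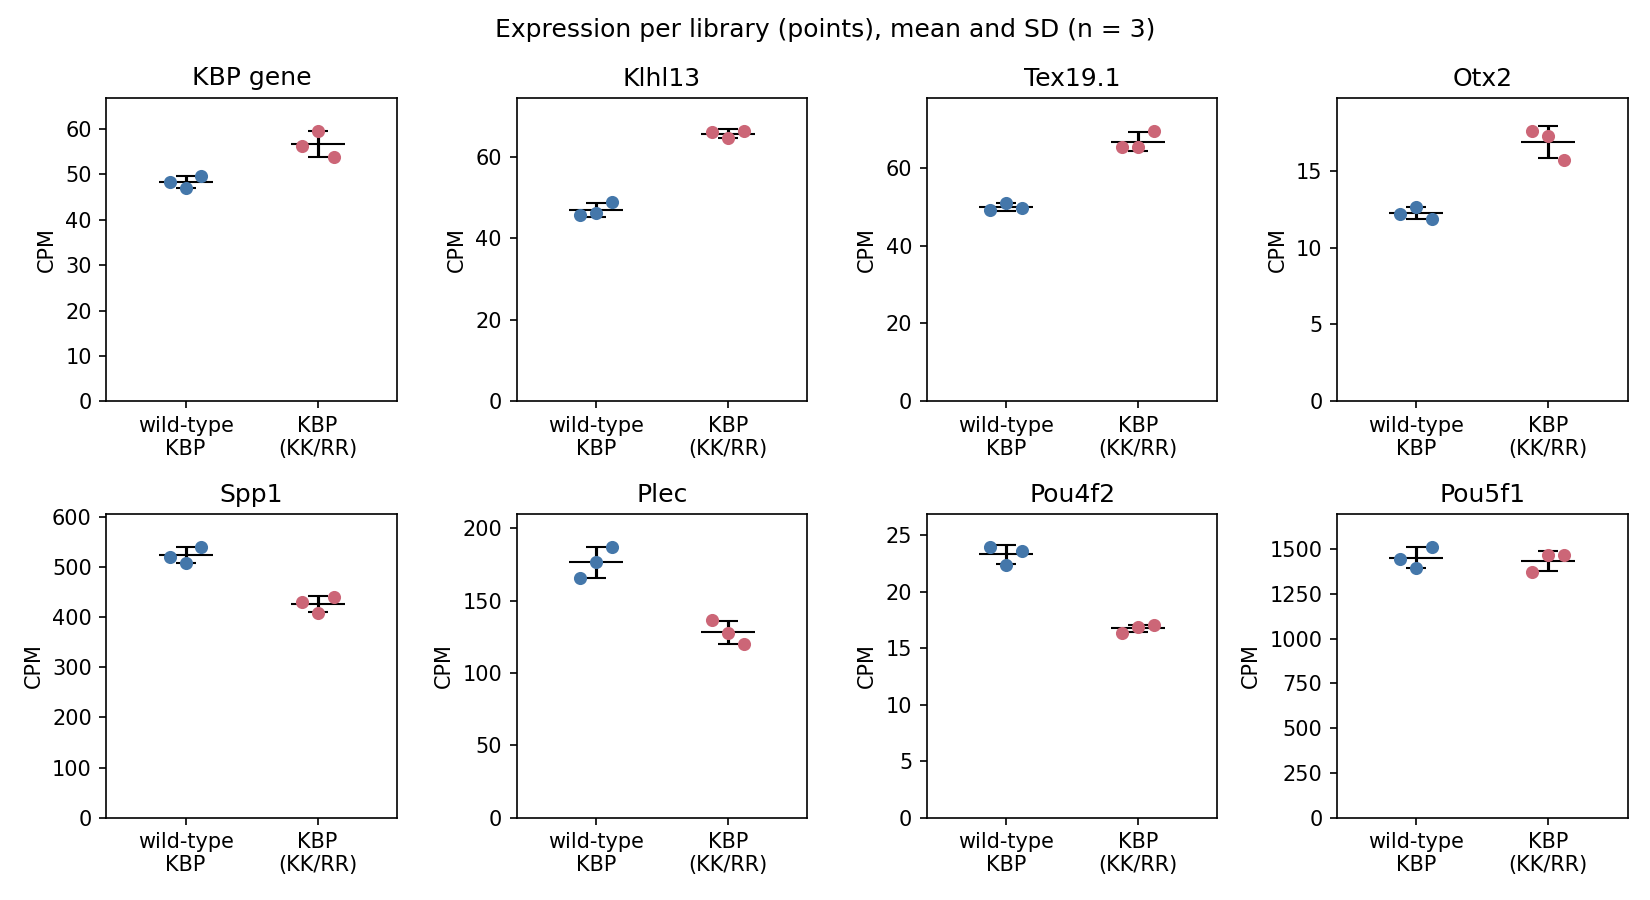
Expression in CPM of 8 genes in each library (points), with the mean and SD of 3 libraries per group; the vertical axes start at 0. Klhl13, Tex19.1, Otx2 and the KBP gene sat higher in the KBP(KK/RR) libraries, Spp1, Plec and Pou4f2 lower, and the values of Pou5f1 overlapped.

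The core pluripotency genes gave no call. Pou5f1 measured 1451 ± 58.9 CPM in wild-type KBP and 1435 ± 55.8 CPM in KBP(KK/RR) cells (log2 fold change -0.02, SE 0.04). Nanog measured 313 ± 9.93 and 334 ± 9.61 CPM (0.10, SE 0.04), and Sox2 386 ± 14.3 and 400 ± 21.9 CPM (0.05, SE 0.04). Their edgeR adjusted p were 0.865, 0.191 and 0.566. The sign for Pou5f1 was positive with upper-quartile scaling and without wild-type KBP replicate 3 or KBP(KK/RR) replicate 4. Of 37 tested members of the pluripotency list, 2 rose and 5 fell (5 and 6 adjusted over the list alone). The fallers included Spp1, the secreted phosphoprotein osteopontin (524 ± 15.9 to 427 ± 16.4 CPM, log2 fold change -0.30), and the naive-state transcription factor gene Tfcp2l1 (332 ± 9.71 to 271 ± 19.3 CPM, -0.29). Tfap2c rose from 35.1 ± 1.56 to 44.2 ± 2.51 CPM (0.33). The list was not called as a whole (camera adjusted p = 0.455). Of 23 primed epiblast genes, which mark cells after implantation, 8 rose and 1 fell (11 and 1 adjusted over the list alone). Otx2 rose from 12.2 ± 0.384 to 16.9 ± 1.03 CPM (log2 fold change 0.46) and Zic2 from 18.8 ± 0.620 to 24.6 ± 0.827 CPM (0.39), whereas Etv4 fell from 139 ± 1.96 to 117 ± 7.37 CPM (-0.25). This list was called higher with the preset correlation (camera adjusted p = 7.55e-06), with an adjusted p = 0.271 with an estimated correlation.

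Markers of other cell types moved in different directions. Of 19 primitive endoderm genes 0 rose and 3 fell (0 and 5 adjusted over the list alone): Col4a1 (111 ± 9.94 to 92.9 ± 4.20 CPM, log2 fold change -0.25), Col4a2 (-0.21), both basement membrane collagens, and the receptor gene Pdgfra (-0.68). The list was called lower (camera adjusted p = 1.51e-04; adjusted p = 0.457 with an estimated correlation). Its median log2 fold change was -0.19, and -0.12 with a trend on length and GC content removed (camera adjusted p = 9.11e-04). Of 16 primitive streak and mesendoderm genes, T, the gene for brachyury, rose from 4.37 ± 0.511 to 6.17 ± 0.4004 CPM (2 rose adjusted over the list alone), and the list was called higher (camera adjusted p = 0.0133; adjusted p = 0.271 with an estimated correlation). Of 18 neural genes 1 fell, Ncam1 (-0.22), and of 18 fibroblast or feeder genes 1 rose, Tagln (0.23), with the same counts adjusted over the list alone. Of 14 trophectoderm genes 0 were called by edgeR (1 rose and 2 fell adjusted over the list alone), with Rhox6 at a log2 fold change of 0.67 and an adjusted p of 0.0728. These 3 lists had camera adjusted p of 0.959, 0.294 and 0.602. The fibroblast or feeder list was called higher without wild-type KBP replicate 3 (0.0116) and with a trend on length and GC content removed (0.0438). Among the trophectoderm genes 4 had an unadjusted p under 0.05, and DESeq2 called 0 of the 5 to which it gave an adjusted p.

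The primitive endoderm calls were not stable when single libraries were left out, and no 1 library accounted for them. That of Col4a1 was lost without wild-type KBP replicate 3 (edgeR adjusted p = 0.0613) or KBP(KK/RR) replicate 5 (0.0866) or 6 (0.114). That of Pdgfra was lost in each omission except wild-type KBP replicate 1 (0.0605 to 0.181), and that of Col4a2 in each except KBP(KK/RR) replicate 4 (0.0583 to 0.255). With a trend on length and GC content removed, Col4a1 and Col4a2 had log2 fold changes of -0.12 and -0.06 (adjusted p 0.104 and 0.577). Col4a2 was also not called in DESeq2 (0.0702) or with upper-quartile scaling (0.0633). The Ncam1 call was lost without wild-type KBP replicate 1 or 2 or KBP(KK/RR) replicate 5 or 6 (0.0537 to 0.109). That of Tagln was lost without wild-type KBP replicate 2 or 3 or KBP(KK/RR) replicate 4 or 6 (0.0581 to 0.255) and in DESeq2 (0.0680). The T call was lost without wild-type KBP replicate 3 (0.0719) or KBP(KK/RR) replicate 6 (0.121). The mesendoderm list lost its call without wild-type KBP replicate 1 (0.0783) or KBP(KK/RR) replicate 6 (0.104).

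Of 17 tested genes of the 2-cell-like state, a rare state of ES cell cultures, 5 rose in KBP(KK/RR) cells and 0 fell (10 and 0 adjusted over the list alone), 16 of 17 had a positive log2 fold change, and the median was 0.54. Zscan4a rose from 2.27 ± 0.190 to 3.67 ± 0.326 CPM (log2 fold change 0.71), Zscan4c from 2.70 ± 0.0561 to 4.13 ± 0.315 CPM (0.61) and Zscan4d from 2.46 ± 0.202 to 3.56 ± 0.395 CPM (0.55). The list was called higher (camera adjusted p = 1.36e-07; adjusted p = 0.116 with an estimated correlation). An unadjusted p under 0.05 was reached by 11 members. DESeq2's filter on mean counts left an adjusted p to 2 of the 17, and neither was called. Of 19 germ cell genes 2 rose and 0 fell, over all genes and adjusted over the list alone: Tex19.1, a germline gene also expressed in ES cells (49.9 ± 0.955 to 66.7 ± 2.47 CPM, log2 fold change 0.42), and Tuba3a (0.41). That list was called higher (camera adjusted p = 6.31e-04; adjusted p = 0.271 with an estimated correlation). Of 34 imprinted genes 2 rose and 0 fell, also over the list alone: Gab1 (189 ± 4.06 to 224 ± 5.98 CPM, 0.24) and Impact (0.16), with a camera adjusted p of 0.445 for the list. The Zscan4 genes are close copies whose reads the counting could divide, so their single values are uncertain. The Zscan4a call was lost without KBP(KK/RR) replicate 6 (edgeR adjusted p = 0.0562). That of Zscan4d was lost without wild-type KBP replicate 2 (0.169) or 3 (0.0678) or KBP(KK/RR) replicate 6 (0.197). That of Tuba3a was lost without wild-type KBP replicate 2 (0.123) or KBP(KK/RR) replicate 4 (0.0573) or 5 (0.0513). That of Impact was lost without wild-type KBP replicate 1 (0.0704), 2 (0.140) or 3 (0.0739) or KBP(KK/RR) replicate 6 (0.188).

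**Figure D2:**
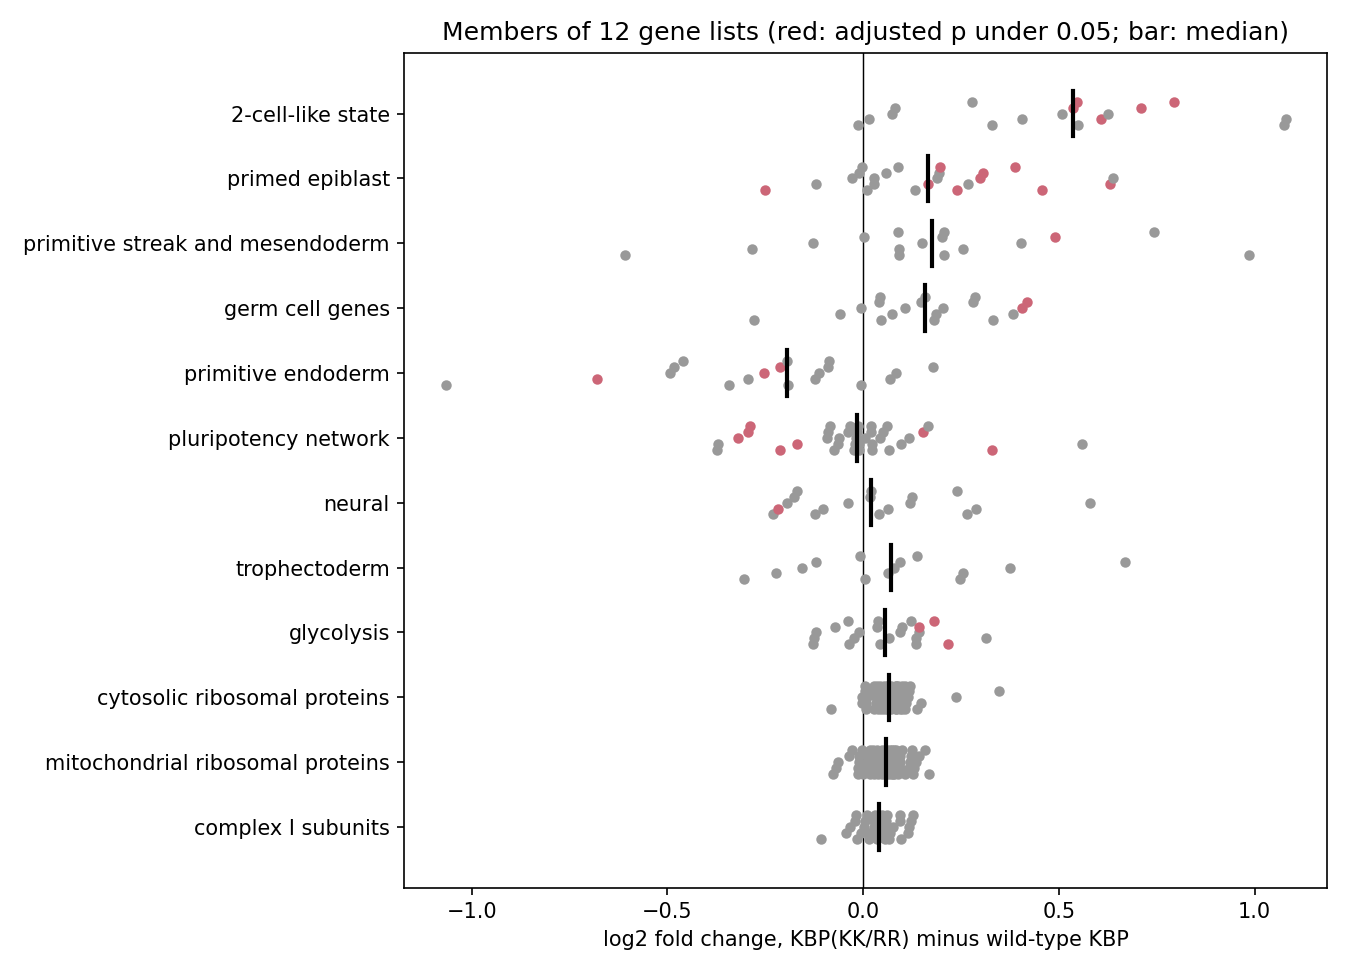
Log2 fold change (KBP(KK/RR) minus wild-type KBP) of each tested member of 12 gene lists, as points that are red where the edgeR adjusted p was under 0.05; black bars are list medians. The median was 0.54 for the 2-cell-like genes, 0.17 for primed epiblast genes and -0.19 for primitive endoderm genes, while ribosomal and complex I genes lay close together near 0.

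Nuclear genes of mitochondrial proteins differed by small amounts. Of 42 subunits of complexes II to V, 1 rose, the ATP synthase subunit gene Atp5f1 (268 ± 5.61 to 296 ± 5.16 CPM, log2 fold change 0.15), and of 35 import and membrane genes 1 rose, Grpel1 (0.15; 2 adjusted over the list alone). Of 35 complex I genes and 76 mitochondrial ribosomal protein genes 0 were called by edgeR, over all genes or over the list alone, with Ndufv2 at 0.13 and Mrpl11 at 0.16 (adjusted p 0.109 and 0.0615), and the same held for 23 tricarboxylic acid cycle genes, with Mdh1 at 0.14 (0.0611). In these 3 lists 7, 13 and 5 genes had an unadjusted p under 0.05, and DESeq2, with an adjusted p for all of them, called 0. Some settings brought single genes past the threshold. Mrpl11 passed with upper-quartile scaling (0.0403), with a trend on length and GC content removed (0.0283) and without KBP(KK/RR) replicate 4 (0.0261), and Mrpl13 with that scaling (0.0455) and that trend removed (0.00774). Mrpl45 passed without KBP(KK/RR) replicate 4 (0.0241). Mdh1 passed with upper-quartile scaling (0.0356), with library totals (0.04999) and without KBP(KK/RR) replicate 4 (0.0270). With the trend removed, 2 mitochondrial ribosomal genes were called higher. Camera called these 5 lists higher. The median log2 fold change was 0.03 for complexes II to V (adjusted p = 0.0133, and adjusted p = 0.493 with an estimated correlation) and 0.04 for complex I (0.0133 and 0.493). It was 0.06 for import (2.06e-04 and 0.457), 0.06 for mitochondrial ribosomal proteins (7.55e-06 and 0.457) and 0.04 for the acid cycle (0.0133 and 0.457). Of 29 biogenesis regulators 1 fell, Mterfd2 (now Mterf4, -0.28). Of 23 fission, fusion, transport and turnover genes 1 rose, Bnip3, a mitophagy receptor gene (29.2 ± 1.91 to 38.1 ± 1.597 CPM, 0.38). Of 39 kinesin motor genes 2 fell, Kifc3 (97.3 ± 2.57 to 73.8 ± 5.83 CPM, -0.40) and Kif26a (-0.28), with the same counts over each list alone. These 3 lists were not called (camera adjusted p 0.650, 0.106 and 0.602). With a trend on length and GC content removed, complex I (adjusted p = 0.953) and the acid cycle (0.378) lost their calls, complexes II to V turned to the lower side (0.937), and Atp5f1 (0.0750) and Kif26a (0.250) lost theirs. The medians of the mitochondrial ribosomal and import lists were then 0.03 and 0.04 (camera adjusted p 0.0330 and 0.0188). The calls of complex I and complexes II to V were lost without KBP(KK/RR) replicate 6 (0.179 and 0.180) or wild-type KBP replicate 3 (0.0590 and 0.0710). Those of the acid cycle (0.0687) and Mterfd2 (0.0671) were lost without KBP(KK/RR) replicate 6. That of Kif26a was lost without wild-type KBP replicate 3 (0.0581) or KBP(KK/RR) replicate 6 (0.0777). Those of Atp5f1 (0.0546 to 0.189) and Grpel1 (0.0629 to 0.198) were lost in each omission except KBP(KK/RR) replicate 4.

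Glycolysis genes included 3 that rose and 0 that fell among 22 (8 and 1 adjusted over the list alone): Tpi1 (325 ± 17.5 to 378 ± 13.9 CPM, log2 fold change 0.22) and the lactate dehydrogenase genes Ldhb (0.18) and Ldha (0.14). Of 18 hypoxia response genes Bnip3 and Ddit4 (53.1 ± 0.548 to 62.5 ± 3.46 CPM, 0.23) rose (3 over the list alone), and of 20 p53 target genes Plk2 rose (0.17; 4 over the list alone). Slc7a5, an amino acid transporter gene, was the member that fell among 26 genes of the unfolded protein and integrated stress response (365 ± 23.3 to 314 ± 5.13 CPM, -0.22; 2 over the list alone). Of 24 cholesterol genes 0 rose and 1 fell (0 and 2 adjusted over the list alone). All 79 cytosolic ribosomal protein genes and 14 heat shock genes lay short of the edgeR threshold, over all genes and over the list alone, with 76 and 14 positive log2 fold changes, Rpl5 at 0.11 (adjusted p = 0.0803) and Hspd1 at 0.09 (0.219). In these 2 lists 24 and 2 genes had an unadjusted p under 0.05, and DESeq2 called 0 of the 74 and 11 to which it gave an adjusted p. Rpl5 passed with upper-quartile scaling (0.0465). Camera called glycolysis higher (adjusted p = 0.0253, and adjusted p = 0.563 with an estimated correlation), as well as hypoxia (0.0133 and 0.271) and p53 targets (0.0253 and 0.457). It also called cytosolic ribosomal proteins (1.36e-07 and 0.493) and heat shock (0.0116 and 0.457) higher. The stress response (0.0119 and 0.493) and cholesterol (0.0253 and 0.457) were called lower. The median log2 fold change of the cytosolic ribosomal genes, whose transcripts are short, was 0.07, and 0.03 with a trend on length and GC content removed (camera adjusted p = 0.0178), when 2 of them were called higher. None of the 18 lists called with the preset correlation was called with an estimated correlation. The estimated correlation was 0.0019 for the 2-cell-like list, -0.026 for hypoxia and -0.021 for mesendoderm, under the preset 0.01. A higher correlation therefore does not account for the loss of these calls. The degrees of freedom, taken from the 6 libraries under an estimated correlation, also set these p-values apart. A call lost under that setting is thus not evidence that correlation within the list gave it. What each change contributed to the losses was not tested.

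The calls of Tpi1 (edgeR adjusted p = 0.0671) and Slc7a5 (0.0614) were lost without KBP(KK/RR) replicate 6. That of Ddit4 was lost without KBP(KK/RR) replicate 5 (0.0570) or 6 (0.0981). Those of Ldhb (0.0595 to 0.141) and Ldha (0.136 to 0.208) were lost without wild-type KBP replicate 1 or 2 or KBP(KK/RR) replicate 5 or 6. That of Plk2 was lost in each omission except KBP(KK/RR) replicate 4 (0.0587 to 0.124). Among the lists, glycolysis was lost without wild-type KBP replicate 1 (camera adjusted p = 0.170) or 2 (0.0645) or KBP(KK/RR) replicate 5 (0.110) or 6 (0.107). The p53 targets were lost without wild-type KBP replicate 1 (0.0953) or 2 (0.0645) or KBP(KK/RR) replicate 6 (0.143), and heat shock without KBP(KK/RR) replicate 6 (0.0563). The stress response and cholesterol were lost without wild-type KBP replicate 3 (0.0797 and 0.108) or KBP(KK/RR) replicate 4 (0.133 and 0.159).

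The remaining lists gave few calls. Of 19 MAPK and FGF feedback genes 2 fell, Etv4 and Spry4 (-0.15; 3 fell over the list alone). Of 14 interferon-stimulated genes 1 fell, Ifitm3 (-0.17), and of 33 cell cycle genes 1 fell, E2f2 (-0.24), with the same counts over each list alone. Of 28 lysosome and autophagy genes 1 rose, Rragd (0.29; 4 rose and 2 fell over the list alone). None of 20 replication-dependent histone genes, close copies whose reads are uncertain, was called by edgeR, over all genes or over the list alone. Among them 1 had an unadjusted p under 0.05, and DESeq2's filter left an adjusted p to 0. Camera adjusted p were 0.552, 0.211, 0.2005, 0.994 and 0.445 in that order. The interferon list was called lower with a trend on length and GC content removed (0.0440). The cell cycle list had a positive median and test and a mean of -0.00187, the lysosome list a positive median and mean and a test on the lower side, the MAPK list a negative median and test and a mean of 0.00255. The Spry4 call was lost in each omission except KBP(KK/RR) replicate 4 (edgeR adjusted p 0.0685 to 0.166), and that of Ifitm3 in each except KBP(KK/RR) replicate 5 (0.0523 to 0.190). Both were also lost with upper-quartile scaling (0.0658 and 0.0575). That of E2f2 was lost without wild-type KBP replicate 1 or any KBP(KK/RR) replicate (0.0610 to 0.128), and with a trend on length and GC content removed (0.0609). That of Rragd was lost without wild-type KBP replicate 2 (0.0882) or 3 (0.129) or KBP(KK/RR) replicate 6 (0.198), and in DESeq2 (0.0863).

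Rn45s, the ribosomal RNA precursor, held 0.219 ± 0.0244% of counts in wild-type KBP and 0.162 ± 0.0111% in KBP(KK/RR) libraries (SD, n = 3; exact two-sided permutation p = 0.1, the smallest possible), and all structural RNAs 0.232 ± 0.0230% and 0.174 ± 0.0110% (exact p = 0.1). Without Rn45s the structural RNAs held 0.0133 ± 0.00153% and 0.0119 ± 3.06e-04% (exact p = 0.4), so the difference in share lay almost wholly in Rn45s. Among 66 tested structural RNA genes 0 were called by edgeR, over all genes or over the list alone, and 56 had a negative log2 fold change. Among them 8 had an unadjusted p under 0.05, and DESeq2 called Rn45s, the 1 gene to which it gave an adjusted p. Camera called the list lower (adjusted p = 0.00158; adjusted p = 0.493 with an estimated correlation). Its median log2 fold change was -0.15, and -0.09 with a trend on length and GC content removed (camera adjusted p = 0.0162). Rn45s had a log2 fold change of -0.44 (edgeR adjusted p = 0.123; 0.00346 without wild-type KBP replicate 1, 0.0207 without wild-type KBP replicate 3, and 0.00844 in DESeq2). The 10 largest genes, led by Eef1a1, held 4.22 ± 0.0726% and 4.43 ± 0.0590% of counts (exact p = 0.1), and total counts did not separate the groups (exact p = 0.9).

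Genes lower in KBP(KK/RR) cells had long and GC-rich transcripts, with a median length of 4686.5 nucleotides and GC content of 55.3%. Genes higher in KBP(KK/RR) cells had 2592 nucleotides and 47.8%, and tested genes that were not called 3313 nucleotides and 49.97%. The median log2 fold change was 0.03 in the fifth of genes with the shortest transcripts and -0.06 in the fifth with the longest. With a trend on length and GC content removed from each library, 693 genes were called by edgeR, 328 higher and 365 lower.

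**Figure D3:**
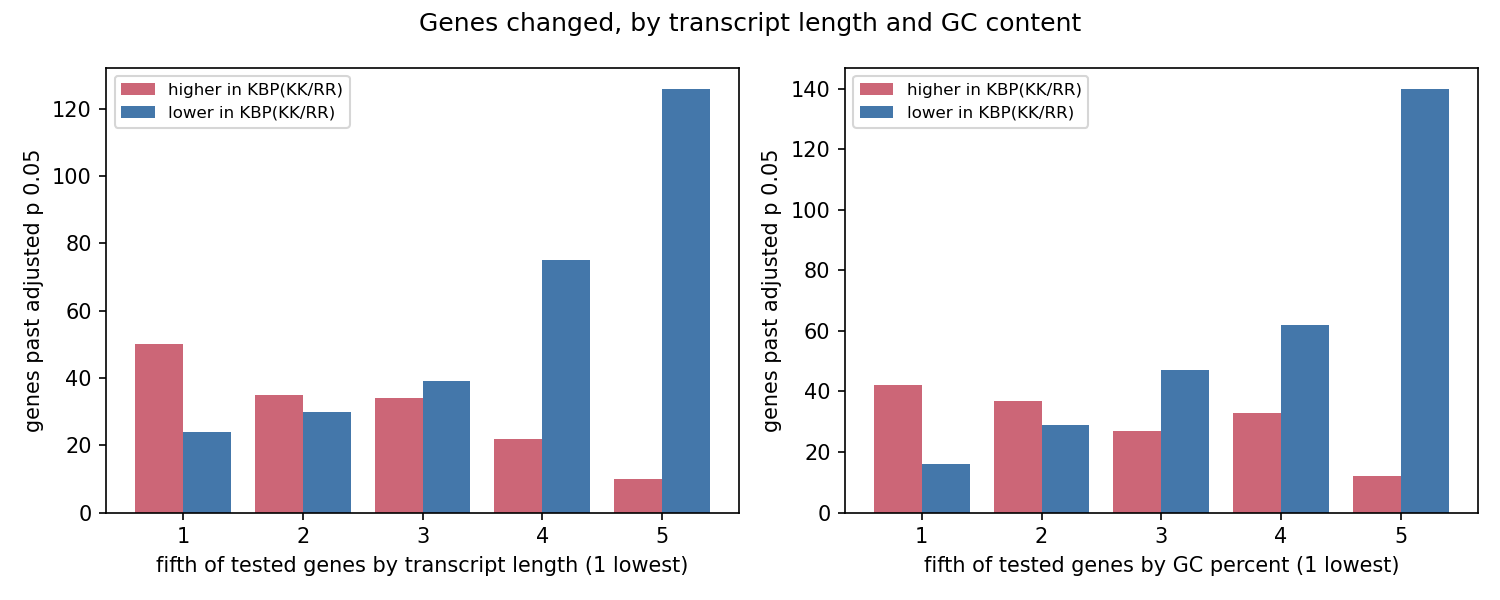
Number of genes past an adjusted p of 0.05, higher (red) or lower (blue) in KBP(KK/RR) cells, in 5 groups of tested genes of like size, by transcript length (left) and by GC content (right). Of the genes with the longest transcripts 10 were higher and 126 lower, and of those with the highest GC content 12 were higher and 140 lower.

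Chromosome medians stayed close to that of all genes. Genes on chromosome 8, among them Nkx6-3, Pou4f2 and Kifc3, had the largest shift, -0.03 on the log2 scale over 644 genes, and chromosome 3 the largest upward shift, 0.03 over 541 genes. The 416 X-linked genes were shifted by 0.02. These lay at percentiles 0, 100 and 100 of random gene sets, but so wide a departure was common: 9 of 20 chromosomes lay below percentile 1 or above percentile 99. Chromosome 8 was shifted by -0.02 without KBP(KK/RR) replicate 4 and with a trend on length and GC content removed, and X by 0.01 without that replicate and by less than 0.01 (0.00149) with a trend on length and GC content removed.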

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

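The length and GC correction, the fit of the same genes without it and the fit on recovered reads were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the groups share no replicate numbers. The main counts were 448 changed genes, 151 higher and 297 lower. They became 966, 284 and 682 without a filter, 270, 78 and 192 with limma-voom, 279, 82 and 197 with limma on the authors' normalized signal, 130, 42 and 88 at an adjusted p of 0.01, 823, 309 and 514 at 0.1, and 1, 0 and 1 in the test against a fold of 1.5 (31 genes at an unadjusted p under 0.05). With length and GC content corrected they were 693, 328 and 365, and 462, 154 and 308 for the same genes uncorrected. DESeq2 called 70 higher genes among 307, and upper-quartile scaling 235 higher among 440. The recovered reads gave 448 calls, all shared with the main ones. With single libraries left out, the counts ran from 122 to 767, 37 to 198 and 85 to 569, part of which follows from fewer samples. No called gene turned sign except 6 of 445 under the correction. Of the lists, 18 were called, 0 with an estimated correlation and 11 to 17 with single libraries left out; complexes II to V turned lower under the correction (adjusted p = 0.937). The log2 fold change of the KBP gene ran from 0.19 to 0.26 with single libraries left out, and was past the threshold in 4 of the 6.

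Of the 56 other called genes named by the rule, 21 kept their call in each omission. Genes short of the threshold that turned sign were, with upper-quartile scaling, Pou5f1 (0.0022), Lonp1 (0.0039) and Ndufv1 (0.013), and under the correction Col5a1 (0.067), Stmn2 (-0.032), Pprc1 (0.014), Lonp1 (0.040), Gabpa (-0.00072), Atp5b (-0.0031) and Dnm1l (-0.018). With single libraries left out, Pou5f1 ran from -0.040 to 0.016, Lonp1 from -0.038 to 0.0088, Gabpa from -0.014 to 0.038, Ndufv1 from -0.042 to 0.033, Dnm1l from -0.012 to 0.058 and Kif5b from -0.037 to 0.041. The difference in total counts ran from -1139670 to 2874660. The cause was not tested for these. Of the 20 largest changes by the naming rule, 16 had no DESeq2 adjusted p, left out by its filter on mean counts, and the effect of depth was not tested.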

Other observations

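The tests of other splits for the number of changed genes, of the share of calls that were lower and of members outside the Zscan4 family, and the correction for length and GC content, were chosen after the results were seen, as was the count of calls per chromosome. X-linked genes, picked out after their values were seen, made up 21 of the 151 genes higher in KBP(KK/RR) cells. Among them, the serine/threonine kinase gene Pim2 rose from 56.8 ± 0.366 to 69.8 ± 3.39 CPM (log2 fold change 0.30, SE 0.05, edgeR adjusted p = 0.00101) and kept its call in each of the 6 omissions. The spermine synthase gene Sms rose from 79.9 ± 2.87 to 93.6 ± 2.52 CPM (0.23) and the MAGE family gene Mageb16 from 20.7 ± 0.998 to 26.3 ± 2.06 CPM (0.36). Both calls were lost without KBP(KK/RR) replicate 6 (adjusted p 0.0588 and 0.0562). So were most of the X-linked higher calls, while Pim2, Klhl13, Rhox5, Usp26 and Nup62cl kept theirs. Of all 151 higher calls, 36 were kept in that omission. The X-linked genes that fell numbered 3. One of them, Med12, a Mediator subunit gene, had a log2 fold change of -0.28, and its call was lost without wild-type KBP replicate 2 (0.0882) or 3 (0.117) or KBP(KK/RR) replicate 5 (0.0507) or 6 (0.0839).

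The 6 samples can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. The real split called 448 genes, so that 1 split, the real one, reached that count. The highest of the other splits called 140 genes, and each of the rest 0. That split grouped wild-type KBP replicate 1 with KBP(KK/RR) replicates 5 and 6. Wild-type KBP replicate 1 and KBP(KK/RR) replicate 4, which it exchanged, lay nearest the middle on component 1 (-6.62 and 6.51). Its calls may thus carry part of the real difference. A difference that cuts across the groups may be present too, and the split cannot tell these apart. In chi-square per degree of freedom, pairs of libraries across groups ran from 3.87 (wild-type KBP replicate 1 with KBP(KK/RR) replicate 5) to 15.2. Pairs within a group ran from 2.69 to 7.19. For gene lists the real split called 18 and the other splits 2 to 9, so the preset correlation also gave list calls in splits that mixed the groups. Each such split still kept 2 libraries of each group together, so these calls need not be false ones. After the length and GC correction the real split called 693 genes and the highest of the other splits 37. In both cases 1 split, the real one, reached the count.

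Of the calls, 66.3% were lower in KBP(KK/RR) cells, and long and GC-rich transcripts were frequent among them. After the correction for a bias between libraries on length or GC content, 61.3% of the lower calls were kept, against a bound of 50% set before that value was seen. By that bound, a bias of the form removed is argued against as their whole cause. Of the higher calls, however, 86.8% were kept, and the corrected fit called more genes, which helps calls to be kept. The kept share is thus weak evidence on the lower calls, and a bias of another form is not excluded. The share of calls that were lower was 52.7% after the correction, but for the same genes lower calls went from 308 to 365 and higher calls from 154 to 328. The share moved because more higher genes were called, so it does not decide on the imbalance, for which bias and a true difference acting on long or GC-rich genes cannot be told apart. With upper-quartile scaling 46.6% of calls were lower.

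X-linked genes were 13.9% of the higher calls and 3.62% of tested genes (one-sided Fisher's exact test, adjusted p = 4.96e-06 over 21 chromosomes and both directions), and chromosome 8 also passed, with 29 of the 297 lower calls (adjusted p = 0.0204). The X-linked excess was noticed in the same calls, so the test describes it and is no independent evidence. A different number of X chromosomes in most cells is argued against. The median of expressed X-linked genes lay 0.0236 above that of all expressed genes (0.0131 to 0.0312 with single libraries left out), under the bound of 0.05. A difference in a small share of cells could give so small a shift and is not excluded. By library, the X-linked median lay furthest from that of all genes in KBP(KK/RR) replicate 4 (0.0424) and wild-type KBP replicate 3 (-0.0315). After the length and GC correction 90.5% of the X-linked higher calls (19 of 21) were kept, close to the 86.8% of all higher calls. That share is thus not particular to X-linked genes and does not decide whether bias gave the excess. X-linked genes were then 7.62% of the higher calls (Fisher's exact p = 4.33e-04). Length or GC bias, a response of some X-linked genes to the mutant, or a difference between the cultures may remain. The response and the cultures were not tested.

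The higher level of 2-cell-like genes may come in part from reads shared between copies of the Zscan4 family. The list also names other gene families, such as Usp17l and Tdpoz, so reads shared between copies in general cannot be judged from it. By a criterion set after the values were seen, the rise was not confined to the Zscan4 family. Outside that family 11 of 12 tested members had a positive log2 fold change (median 0.37) and 2, Tmem92 and Gm8300, were called. Both calls were weak: that of Tmem92 was lost without wild-type KBP replicate 1 (adjusted p = 0.0678) or 2 (0.269) or KBP(KK/RR) replicate 4 (0.0848) or 6 (0.230), and that of Gm8300 without any wild-type KBP replicate (0.0647, 0.149 and 0.0828), without KBP(KK/RR) replicate 6 (0.227) and under the length and GC correction (0.0523). Length or GC bias is argued against, as the list's median log2 fold change was 0.54 before and 0.46 after the correction. No biological explanation was tested. With an estimated correlation, which also changes the degrees of freedom, the list itself was not called (camera adjusted p = 0.116).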
